A study of Drosophila melanogaster with 3 samples.

How the data were processed

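CG11560 is a Drosophila melanogaster gene that was tagged with enhanced green fluorescent protein (eGFP) in transgenic flies. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against GFP was run on whole embryos aged 0 to 24 hours. The labels describe 3 biological replicates of this 1 group, with chromatin sheared by sonication to a size range of 200 to 800 (the unit is not given in the labels). No second group and no control library are among the samples, so the comparisons are between the 3 replicates and between bound regions and the rest of the genome.

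The deposited files are region lists on the dm6 assembly, per the labels and the accompanying records. Each replicate has a ranked list and a shorter thresholded list of its own. The series has further ranked and thresholded lists derived from the alignments of all 3 libraries, of which 1 is marked as conservative, and the sources do not say which replicates or pooled reads were paired in the others. Per the deposited records, every list was made from alignments and 1 further input, taken here to be a control because related tracks are given over a control; the records do not describe it. Regions were ranked by the irreproducible discovery rate (IDR), an estimate of the chance that a region fails to recur between repeats. The aligner, the peak caller and their versions are not given in the sources used here. The thresholded lists were derived from 1 more file than the ranked lists, and the content of that file is not given in the sources used here.

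The score in the deposited lists is a whole number with a maximum of 1000 that restates the IDR. The −log10 values in the deposited ranked lists are those of the same IDR. All scores of the 3 replicates' ranked lists lay within 1 of the score computed from that column, and a score of 830 or more went with an IDR of 0.01 or less to within rounding (a −log10 value of at least 1.999). The lowest score in each thresholded list was 830. The signal value per region is the authors' own, as their peak caller gave it, and was used only to rank regions within a list. A fractional rank is a region's rank by signal divided by the length of its list, so a small value is a strong region. The deposited lists give no p-value per region and no read counts, so the depth of the libraries is unknown.

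Positions were compared with the Ensembl annotation of release 115 (BDGP6.54) and with the Release 6 genome sequence, whose coordinates are those of dm6. No region extended past the end of a chromosome arm. Regions elsewhere (29, 62 and 7 in replicates 1, 2 and 3) entered only the counts, ranks and overlap of the lists. All other analyses were restricted to the arms 2L, 2R, 3L, 3R, 4 and X, which hold 133647856 assembled bases, 13945 protein-coding genes and 19252 transcription start site (TSS) positions of such genes. Coordinates are given 1-based on dm6. Regions of different replicates were joined where their summits lay within 100 bp, and the regions called in all 3 thresholded lists formed the main set. Each joined region took the summit of the replicate with its best fractional rank.

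A region was at a promoter when its summit lay within 500 bp of a protein-coding TSS. Classes were assigned in the order promoter, coding exon, UTR, intron and intergenic, and were compared with the share of arm bases by exact two-sided binomial tests. Members of 40 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and the tRNA and snRNA lists with all other annotated genes apart from transposable elements (18164 genes in all). Of the 549 list entries given by gene symbol, 538 matched the annotation. A promoter was divergent when a protein-coding TSS of the opposite strand lay within 1000 bp upstream. Gene lengths were compared with a two-sided permutation test of 100000 resamples on the mean log2 length. Matches to 36 consensus motifs, and all 8-mers counted on both strands and seen in at least 10 windows, were counted within 100 bp of the summits and in windows of the same size centred 500 bp to a randomly drawn side, which regions shared with the main set kept in the alternatives. These counts were compared by exact two-sided McNemar tests. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Intervals of shares are 95% Wilson intervals and cover counting error only. Neighbouring regions and overlapping promoters are not independent, and a test across regions or genes says nothing of the spread between embryo collections.

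Unless stated otherwise, the gene lists, motifs, tests and alternatives were fixed before the data were examined. So was the rule for names, which covered CG11560, the gene of the nearest TSS for the 25 regions in all 3 lists with the best mean fractional rank, up to 4 bound members of each list past the threshold and at most 2 of each other list. Of the 8-mers, the 5 with the smallest p that shared fewer than 6 bases in a row were named. Alternatives were regions in at least 2 of 3 lists, the conservative list and the longest list of the series, other overlap rules, the 50% of each list with the highest signal, each replicate left out, promoter windows of 200 and 1000 bp, other TSS sets and backgrounds, a divergent distance of 500 bp, motif windows of 50 bp, and windows at unbound promoters placed at the same offset from the TSS. The planned restriction to an IDR of at most 0.01 removed no region, because the lowest score in every thresholded list was already 830.

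The tests were tested on simulated data. All 600 regions planted in 3 lists were recovered. Random gene sets of 800 genes, drawn 20 times, gave 2 calls in 760 list tests, which left out the tRNA and snRNA lists. In random sequence, with the same base frequencies for summit and control windows, 0 of 13077 8-mers passed the threshold. A planted 8-mer came first. Summits and flanks that differ in base composition were not simulated. The ranked lists of the whole series hold 32 columns of values per input that carry no replicate name and were not used. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.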

Results

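CG11560 is a protein-coding gene on chromosome arm 3L, and its eGFP fusion was mapped on the chromatin of whole embryos aged 0 to 24 hours. The 3 biological replicates form 1 group. Their thresholded lists held 2052 regions in replicate 1, 1274 in replicate 2 and 1614 in replicate 3, taken from ranked lists of 109679, 120924 and 126897 regions. The median region width was 344 bp in replicates 1 and 2 and 416 bp in replicate 3. Read numbers are not part of the lists, so the depth of each library is unknown, and differences in list length cannot be set against depth. The longest replicate list was 1.61 times the shortest, and the longest list of the series, with 3351 regions, was 1.49 times the conservative list of 2243 regions.

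At the tagged gene itself (CG11560, FBgn0036249, 3L 12120019 to 12121185), a region was called in replicate 3 and in neither replicate 1 nor replicate 2. It spanned 12119992 to 12120407, with its summit at 12120200, 181 bp downstream of the gene start. By signal it was number 1181 of 1614 in replicate 3. None of the 4 thresholded lists of the series had a region over the gene. In the longer ranked lists, CG11560 had a region in replicate 3 and in 1 list of the series, where it was number 4078 of 147014.

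Most of the best-ranked regions called in all 3 replicates lay just upstream of a TSS. The region at smg, which encodes the translational repressor Smaug, was number 1, 1 and 2 by signal in replicates 1, 2 and 3 (3L 8997811 to 8998303, summit 76 bp upstream of the TSS). Its mean fractional rank was 0.0837% ± 0.0379 (SD, n = 3). Next came Polr1E and Polr2F, which encode RNA polymerase subunits, at 0.216% ± 0.0513 and 0.231% ± 0.0819 (SD, n = 3). Bruce and Diap1, both inhibitors of apoptosis, had regions 114 and 108 bp upstream of their TSSs, with mean fractional ranks of 0.249% ± 0.170 and 0.599% ± 0.231 (SD, n = 3).

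Of the 25 regions with the best mean fractional rank, 23 were at promoters, and the summits of all 23 were upstream of the nearest TSS, at a median of 55 bp (range 6 to 420 bp). Beyond those above, these promoters belonged to EndoGI, CG3638, Atx2, Pomp (a proteasome assembly factor), Usp1, Pp1-87B (a protein phosphatase catalytic subunit), CG13551, Cortactin, CG17065, chico (the insulin receptor substrate), sina (a ubiquitin ligase), PGAP5, MCU (the mitochondrial calcium uniporter), emb (a nuclear export receptor), Pfdn5, Syx17, dos and msl-3 (a member of the dosage compensation complex). At 6 of these promoters a further gene was in the window: CG5087 with smg, CG12818 with Bruce, PRL-1 with EndoGI, NANS with Pp1-87B, fy with emb and BBS1 with msl-3. The remaining regions of the 25 lay away from promoters. The region nearest to zfh1, a zinc finger and homeodomain transcription factor, was intergenic, with its summit 6200 bp downstream of the nearest zfh1 TSS (3R 30789260 to 30789648, ranks 7, 8 and 7). The region at Asator lay in an intron, 679 bp upstream of the nearest TSS (chromosome 4, 486534 to 486914, ranks 16, 23 and 15). The ranks of the 25 regions in the single lists ran from 1 to 41, a range that their choice by mean fractional rank limits.

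Between pairs of replicates, 51.2% to 82.8% of regions were shared. Replicate 2 shared 1055 of its 1274 regions with replicate 1 (82.8%, 95% Wilson interval 80.6 to 84.8), and these were 51.4% of replicate 1 (49.2 to 53.6). Replicate 3 shared 1130 of its 1614 regions with replicate 1 (70.01%, 67.7 to 72.2) and 826 with replicate 2 (51.2%, 48.7 to 53.6). By chance, 0.182% to 0.304% of summits would lie within 100 bp of a summit of the other list. Ranked regions outside the thresholded lists were shared in 0.121% to 0.614% of cases, and the odds ratios of listed against unlisted regions ran from 390 to 875. Across shared regions, which are not independent replicates, Spearman's rho of the fractional ranks was 0.871 for replicates 1 and 2, 0.774 for replicates 1 and 3 and 0.742 for replicates 2 and 3.

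Joining the lists gave 2710 regions, of which 806 were called in all 3 replicates, 614 in exactly 2 and 1290 in 1. The 806 were 39.3% of the list of replicate 1, 63.3% of that of replicate 2 and 49.9% of that of replicate 3. Regions called in 1 replicate alone numbered 662 in replicate 1, 184 in replicate 2 and 444 in replicate 3.

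**Figure D1:**
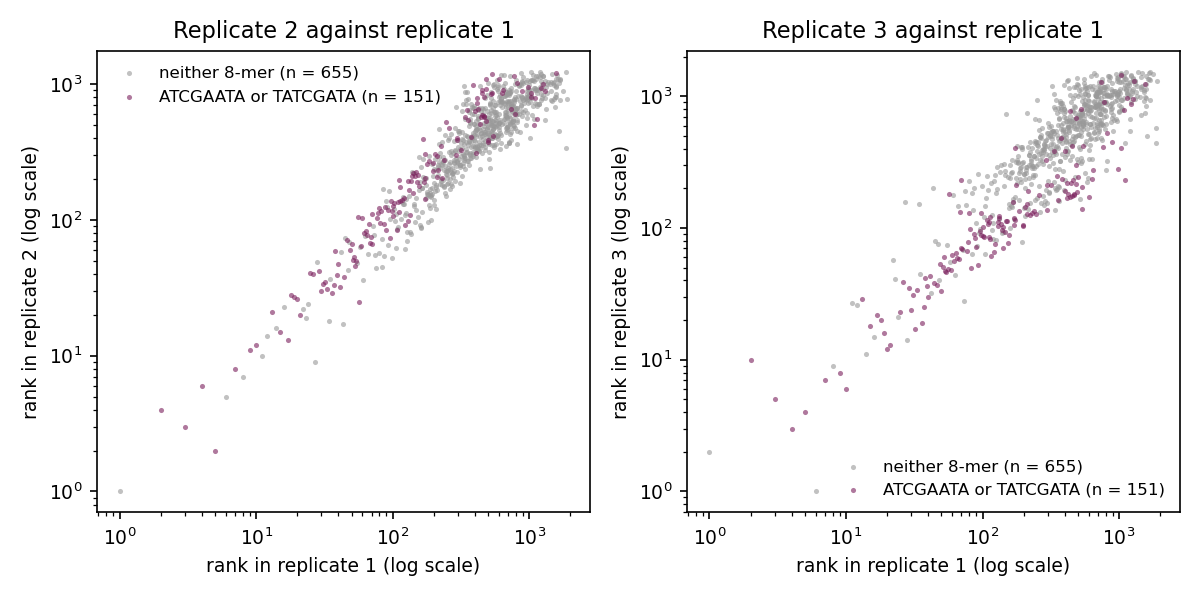
Rank by signal of the 806 regions called in all 3 replicates, in replicate 2 (left) and replicate 3 (right) against replicate 1, on log scales. Each point is a region, coloured by whether ATCGAATA or TATCGATA lies within 100 bp of the summit (n = 151) or neither does (n = 655); of the 151, 108 had a smaller rank number in replicate 3 than in replicate 1, against 207 of the 655.

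Regions called in all 3 replicates were concentrated at the promoters of protein-coding genes. Of the 806, 561 were at promoters (69.6%, 95% Wilson interval 66.3 to 72.7), a class that covers 11.5% of the bases of the chromosome arms, a 6.07-fold excess. Introns held 154 regions (19.1% against 39.4% of bases, exact binomial p = 5.0e-35) and intergenic sequence 86 (10.7% against 29.9%, p = 7.1e-39). Coding exons held 1 region (0.124% against 14.1%, p = 1.3e-51) and UTRs 4 (0.496% against 5.17%, p = 1.1e-13, exact tests). The promoter share was 59.5% in replicate 1, 58.4% in replicate 2 and 70.1% in replicate 3, with a mean of 62.7% ± 6.45 (SD, n = 3).

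Summits of promoter regions were upstream of the nearest TSS in 504 of 561 cases (89.8%), and the median position was 101 bp upstream (quartiles 46 and 169 bp). The promoters of 807 genes held a region, 5.79% of the 13945 protein-coding genes of the arms. Promoter regions on X made up 97 of 561 (17.3%, 14.4 to 20.6), against 17.0% of TSSs on X (exact binomial p = 0.87). In the single lists the X share of promoter regions was 19.0% (p = 0.077), 19.9% (p = 0.045) and 19.7% (p = 0.017) for replicates 1, 2 and 3, by the same exact test.

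**Figure D2:**
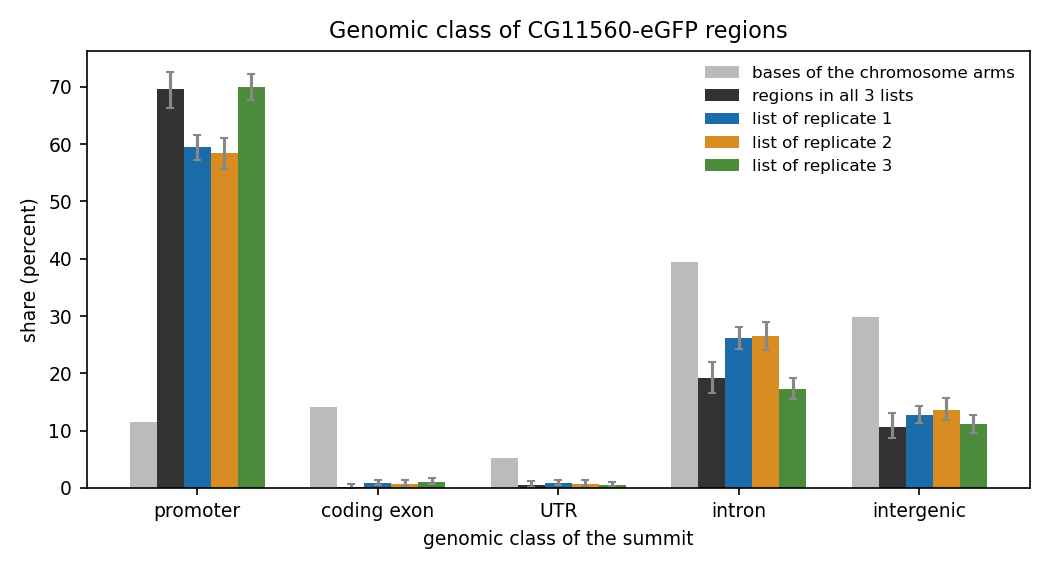
Share in percent of the bases of the chromosome arms (grey), of the 806 regions called in all 3 replicates (black) and of each replicate's list (colours), by genomic class of the summit; error bars are 95% Wilson intervals. Promoters hold 69.6% of the 806 regions and 11.5% of the bases.

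Among the 40 gene lists, genes for splicing factors and for mitochondrial ribosomal proteins had regions at their promoters more often than other genes did. Of 29 splicing genes, 7 had a region called in all 3 replicates (24.1% against 5.75% of other genes, odds ratio 5.22, adjusted p = 0.014, exact test). They included hfp, SmB, Sf3b2 and tra2, whose summits lay 33, 39, 48 and 45 bp upstream of the TSS, with mean fractional ranks of 5.36% ± 2.44, 6.83% ± 3.79, 8.01% ± 2.71 and 13.8% ± 6.93 (SD, n = 3). Of 75 mitochondrial ribosomal protein genes, 11 had a region (14.7%, odds ratio 2.82, adjusted p = 0.037, exact test), among them mRpL41, mRpL45, mRpS10 and mRpS23 with mean fractional ranks of 5.46% ± 3.27, 7.42% ± 3.27, 8.11% ± 3.49 and 8.29% ± 5.09 (SD, n = 3). In the single lists splicing genes were above other genes in replicates 1 and 2 (adjusted p = 0.023 and 0.0074) and did not pass in replicate 3 (0.056), and mitochondrial ribosomal protein genes did not pass in any (0.14, 0.12 and 0.075, exact tests). When only the nearest TSS of each region was counted, neither list passed, with odds ratios of 5.08 for splicing (adjusted p = 0.069) and 1.37 for mitochondrial ribosomal proteins (0.97, exact tests). With the 50% of each list with the highest signal they were 4.14 (0.15) and 3.10 (0.091), again without passing. Mitochondrial ribosomal proteins also missed the threshold with regions in at least 2 lists (odds ratio 1.86, adjusted p = 0.25), the conservative list (2.12, 0.05), promoter windows of 200 and 1000 bp (2.70 and 2.46, both 0.12), and without replicate 2 (2.10, 0.13) or 3 (2.47, 0.061, exact tests).

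Chemoreceptor genes and tRNA genes had fewer regions than other genes. None of 179 chemoreceptor genes had a region in any replicate (adjusted p = 0.00069 for regions in all 3, exact test). Of 290 tRNA genes, 1 had one, tRNA:Tyr-GTA-1-8 (0.345% against 4.77%, odds ratio 0.0691, adjusted p = 0.00069, exact test). Among genes with a ranked region, where 39 tRNA genes remain, this result did not pass (odds ratio 0.212, adjusted p = 0.48, exact test). With the 50% of each list with the highest signal, neither list passed (adjusted p = 0.053 for both, exact tests). Cuticle protein genes had 0 of 96 in all 3 lists (adjusted p = 0.053, exact test) and were below other genes in each single list (adjusted p = 9.1e-05, 0.018 and 0.00037, exact tests).

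Cytosolic ribosomal protein genes differed between the replicates. Of 93, 28 had a region in replicate 1 (30.1%, interval 21.7 to 40.1), 9 in replicate 2 (9.68%, 5.17 to 17.4) and 33 in replicate 3 (35.5%, 26.5 to 45.6), against 11.6%, 6.83% and 10.6% of other genes, with exact McNemar p = 3.8e-06 and 1.2e-07 for replicates 1 and 3 against replicate 2. The list was above other genes in replicate 1 (adjusted p = 2.0e-05) and replicate 3 (8.8e-09), and it did not pass in replicate 2 (0.63) or for regions in all 3 lists (9 of 93, 0.38; exact tests). Without replicate 2, it passed (22 of 93, adjusted p = 8.3e-05, exact test). It also passed with regions in at least 2 lists (22 of 93, 0.00044), the conservative list (29 of 93, 6.1e-05) and the longest list (35 of 93, 5.9e-07, exact tests). The list passed in no other alternative. RpS19a and RpL23A, both with summits 99 bp upstream, had its best mean fractional ranks among the regions in all 3 lists. Genes of the highly transcribed list, which shares RpL32, RpLP0 and RpS3 with the ribosomal list, were also above other genes in replicate 1 (9 of 22, adjusted p = 0.0039, exact test) and replicate 3 (7 of 22, 0.044).

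In all, 36 of the 40 lists did not pass the threshold for regions in all 3 replicates. Mediator genes had 5 of 29 (MED19 and MED10, adjusted p = 0.15, exact test), Atg autophagy genes 4 of 20 (Atg17 and Atg9, 0.15) and insulator and architectural genes 4 of 24 (Chro and SMC3, 0.23). The Hox genes had 0 of 8 and the lists of gap and maternal, pair-rule and segment polarity, and dorsoventral and mesoderm patterning genes 0 of 15, 0 of 17 and 0 of 17. Histone genes had 3 of 115 (adjusted p = 0.41, exact test) and were below other genes in replicates 1 and 3 (0.0046 and 0.017). Only 3 histone genes had a ranked region in each replicate, and among genes with one the direction turned, since all 3 had a called region (adjusted p = 0.021, exact test). Genes for RNA polymerase II and general factors were above other genes in replicate 1 (12 of 43, 0.017, exact test). The snRNA genes had 0 of 32 (adjusted p = 0.85, exact test). Single bound members of other lists included elav among neuronal genes, gro in the Notch pathway, and ph-p and E(z) among Polycomb group genes.

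**Figure D3:**
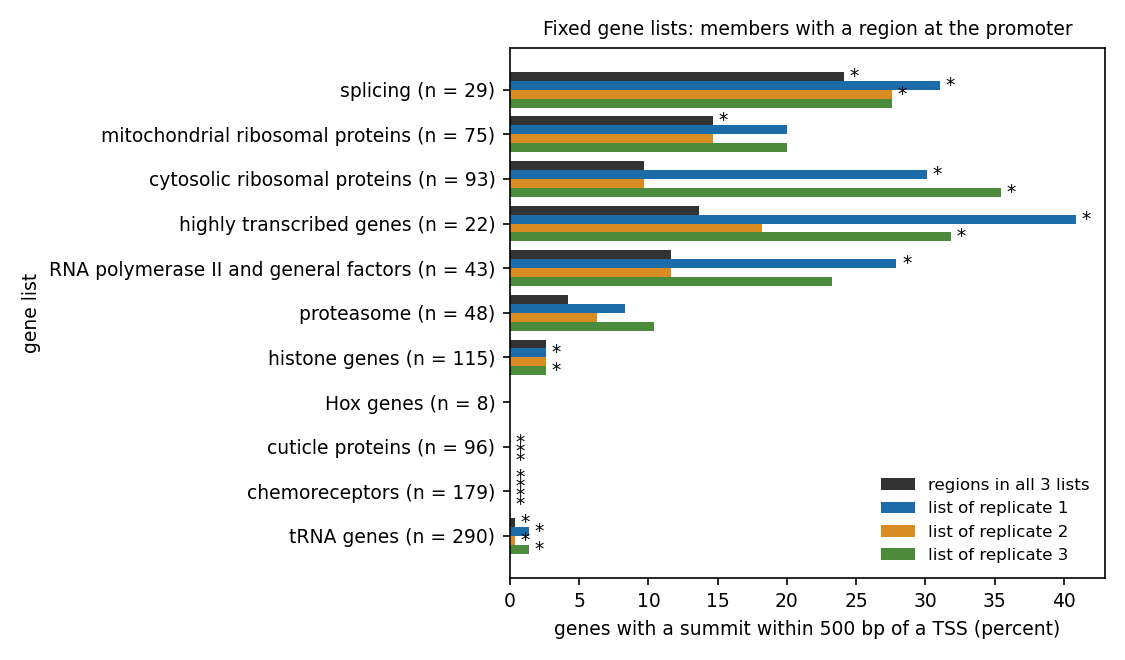
Percent of the members of 11 gene lists with a summit within 500 bp of a TSS, for regions called in all 3 replicates (black) and for each replicate's list (colours); a star marks a list past the adjusted p threshold of 0.05, above or below other genes. Cytosolic ribosomal protein genes stand at 30.1%, 9.68% and 35.5% in replicates 1, 2 and 3.

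Bound promoters were often divergent, and bound genes were longer. Of the 807 genes with a region at the promoter, 543 had a TSS of the opposite strand within 1000 bp upstream (67.3%), against 34.3% of the 13138 other genes (odds ratio 3.94, Fisher's exact p = 4.8e-76). The odds ratios of the single replicates were 4.20, 3.79 and 4.14. The median length of bound genes was 3275 bp, and the mean log2 length was 0.59 above that of other genes, a 1.51-fold difference (permutation p = 1.0e-05, the smallest that the permutations can give). Single replicates gave log2 differences of 0.62, 0.62 and 0.59, and a promoter window of 200 bp gave 0.34. A gene with several annotated TSSs can be bound at any of them, and the length test did not match genes for TSS number. A summit between paired genes counts for both of them, so bound genes are not independent of each other, and a gene can be bound through the region of its partner. With only the nearest TSS of each region counted, a setting chosen after seeing the data, the odds ratio fell to 2.09 (Fisher's exact p = 3.2e-17).

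The 8-mer ATCGAATA had the smallest p near the summits of the 806 regions. It lay within 100 bp of 115 of 806 summits (14.3%, interval 12.02 to 16.9) and in 6 of 806 flanking windows (exact McNemar, adjusted p = 6.0e-24, first of 10434 8-mers). It was present at Polr1E, Polr2F, EndoGI, Diap1, Pomp, chico, emb and msl-3 and absent at smg, Bruce and Atx2, and 16 of the 25 best-ranked regions had it. Apart from 8-mers that share most of its bases, ATCGATAG followed with 64 windows against 5 (adjusted p = 6.0e-12), and then the AT-rich ATTTAAAA (129 against 36, 1.7e-11), AAAATATT (116 against 33, 4.6e-10) and AATAAATA (105 against 32, 4.5e-08), by the same exact test. By p, ATCGAATA was number 3, 1 and 6 in the lists of replicates 1, 2 and 3 and number 6 in the conservative list, and ATCGATAG was number 1 in replicate 3 and in the conservative list. In all, 387 8-mers were more frequent at summits and 135 less frequent.

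Chosen after seeing the data, the position and place of ATCGAATA were counted further. It was in 59 of the 100 regions with the best mean fractional rank (59.0%, interval 49.2 to 68.1), in 24 of the next 100, in 20 of the 200 after those and in 12 of the last 406 (2.96%, 1.70 to 5.10), with an odds ratio of 47.2 for the first 100 against the last 406 (Fisher's exact p = 1.1e-37). At promoters 106 of 561 regions had it (18.9%) and elsewhere 9 of 245 (3.67%), an odds ratio of 6.11 (exact p = 6.7e-10). The median distance of its matches from the summit was 26 bp, and 57.7% of matches were within 30 bp, against 30.3% for even spacing. ATCGAATA was in 14.3% of the regions in all 3 lists, 4.03% of those in exactly 2, and 1.08%, 2.86% and 4.35% of those in replicate 1, 2 or 3 alone.

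**Figure D4:**
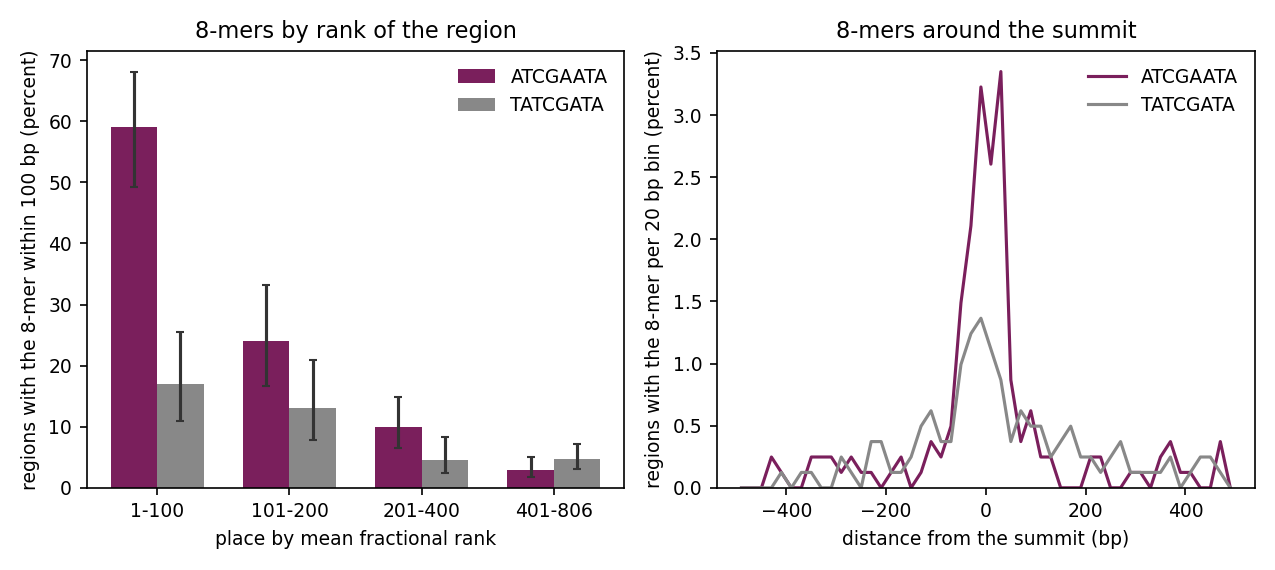
Left, percent of regions with ATCGAATA or TATCGATA within 100 bp of the summit, by place of the region by mean fractional rank, with 95% Wilson intervals; right, percent of the 806 regions with each 8-mer per 20 bp bin, by distance from the summit in bp. ATCGAATA falls from 59.0% in the first 100 regions to 2.96% in the last 406.

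Of the 36 consensus motifs, 9 were more frequent at summits than in the flanks. The DNA replication-related element TATCGATA, the site of the factor DREF, was in 58 of 806 windows against 4 (adjusted p = 2.1e-13, exact test). Ohler motif 7, a core promoter motif, was in 154 against 51 (2.1e-13), the TATA box in 122 against 56 (3.2e-06), the ZIPIC site in 24 against 2 (7.6e-05), Ohler motif 6 in 85 against 40 (9.6e-05) and the M1BP site in 23 against 4 (0.0016). The homeodomain (133 against 89), GATA (295 against 237) and Tinman (65 against 40) sites also passed, and the Zeste, GAGA, Su(H) and E2F sites were less frequent at summits. The flanks were not matched for base composition, and several of the sites higher at summits are AT-rich. A difference in AT content between summits and flanks therefore stays open for the higher and the lower sites. In the single lists Su(H) passed in none, and Tinman and E2F passed in replicate 1 alone. Each count rests on 1 random choice of the flank side. In 1000 other choices, drawn after seeing the data, Tinman passed in 25, E2F in 133, Su(H) in 514, GAGA in 631, GATA in 866 and homeodomain in 987, and the other 7 sites passed in all of them. With the flanks kept, Tinman did not pass without replicate 2 or 3 (adjusted p = 0.055 and 0.11), E2F without replicate 2 (0.2) or Su(H) without replicate 1 or 3 (0.12 and 0.11, exact tests). Over 13 alternatives, Tinman kept its call in 2, Su(H) in 6, GATA in 8, E2F in 8 and GAGA in 9.

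At the 561 promoter regions, 8 of these 9 motifs, all but Tinman, were more frequent at summits than in the same flanks, though GATA passed there in 263 of 1000 other choices of the side. Against windows at promoters without a region, placed at the same offset from the TSS, 2 of the 9 passed. These control promoters were 1 random draw that was not repeated, so calls and misses near the threshold are uncertain. They were not matched for activity or divergence, so a motif of active or of divergent promoters stays open. Ohler motif 7 was in 132 of 561 promoter regions against 50 windows (adjusted p = 3.7e-09, exact test) and the ZIPIC site in 23 against 6 (0.027). TATCGATA was in 54 against 30 (0.085), Ohler motif 6 in 59 against 34 (0.085) and the TATA box in 90 against 72 (0.36). The homeodomain site was in 94 against 73 (0.22) and the GATA site in 189 against 182 (0.97). None of the sites less frequent at summits passed here, with Zeste in 109 against 144 (0.085, exact tests). ATCGAATA was in 106 of the 561 promoter regions and in 1 of the 561 windows at promoters without a region (exact McNemar p = 1.3e-30). ATCGATAG, which overlaps TATCGATA, was in 61 against 24 and passed (adjusted p = 0.01, exact test). ATTTAAAA (95 against 37, 6.1e-05) and AAAATATT (87 against 44, 0.022) passed as well, and AATAAATA did not (77 against 42, 0.076, exact tests).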

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

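The comparison with promoters at the same offset was set before the lists were seen. The other tests of this part were chosen after the lists had been examined, and those of base composition, calls at promoters of other genes, promoter location, and GC content with TSS distance after the pattern they address had been seen in the same data. The design has 1 group, so no biological explanation was tested for any pattern. The regions left out of the thresholded lists were first among the patterns to be weighed and were then given without an explanation, after their results had been seen, and the count of regions with most bases repeat-masked was added after the test of the median.

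A signal outside the thresholded lists drew attention. In the ranked lists, 32 regions reached the score of 830 in all 3 replicates and were in none of the 3 thresholded lists. Of these, 24 were on the chromosome arms and 12 of the 24 at promoters. The best ranked lay 90 bp upstream of gpp, a histone methyltransferase gene, with ranks 11, 15 and 8, and had ATCGAATA. Others were at Sin3A, CG8176, larp and chic, and 3 each were nearest to cbt and tara. The median share of repeat-masked bases within 100 bp of the summit was 18.9%, against 21.4% for regions called in all 3 replicates (permutation p = 0.44), and 1 of the 24 had over 50% of its bases masked (4.17%, interval 0.739 to 20.2), against 2.85%. Another of the 24 lay within 20 kb for 9 of them, above the highest count of 4 in 1000 random draws. The left-out regions were therefore closer together than drawn regions, and the cause was not tested. Over all regions at this score, those left out numbered 149, 152 and 75 in replicates 1, 2 and 3 (6.77%, 10.7% and 4.44%).

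ATCGAATA was concentrated near the summits of the best-ranked regions. A sequence common to promoters of any kind is argued against by the share of ATCGAATA at promoter regions. That share was 106 times the share at promoters without a region (106 of 561 against 1 of 561). The 8-mer was picked on these same regions and the control windows were 1 random draw, so the size of this ratio is uncertain. The control promoters were not matched for activity or divergence, so a sequence of active or of divergent promoters stays open. Base composition is argued against on 3L, 3R and X: ATCGAATA had the smallest p on 2L, 2R and 4, and on the arms not used for that choice its ratio of summit to flank windows was 28.2 (70 against 2, with 0.5 added to each), above the highest ratio of 21 and the median of 1.55 among 351 8-mers of its composition that shared fewer than 6 bases in a row with it. On 2L, 2R and 4, where its ratio was 10.11 (45 against 4), above 96.7% of 121 such 8-mers (median 1.59, highest 27), base composition stays open, because the 8-mer with the smallest p on the other arms was ATTCGATA, which overlaps it. Recognition of this sequence by CG11560-eGFP or a protein bound with it is a hypothesis, and a signal that other tagged proteins would share stays open as well, since the lists hold no control immunoprecipitation.

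Cytosolic ribosomal protein promoters were called less often in replicate 2, as were those of other genes. The length of the lists is argued against as the whole cause, since at the length of the shortest list 20, 9 and 30 of 93 genes had a region in replicates 1, 2 and 3 (exact McNemar p = 0.00098 and 9.5e-07 against replicate 2), beside 8.31%, 6.83% and 9.25% of other genes. Loss of regions that reached the score of 830 is argued against too: of the 14 genes called in replicates 1 and 3 and not in 2, 0 (0%) had such a region in replicate 2, and 11 had a ranked region there, at a median rank of 14635 of 120924. A lower number of called promoters of any gene in replicate 2 stays open, since at equal length the 11 and 21 ribosomal genes called in 1 list of a pair alone were all in replicates 1 and 3, as were 76.9% and 74.6% of the other genes so called (exact test, adjusted p = 1 and 0.14 over 38 lists). Library depth, the strength of the immunoprecipitation and the ages within each embryo collection may differ between the replicates and stay open, as the lists give none of them.

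Regions with ATCGAATA or TATCGATA ranked higher in replicate 3 than in replicate 1, relative to other regions, a pattern found in the plot of ranks after many motifs and 8-mers had been compared between the groups of points seen there. The mean log2 ratio of rank in replicate 3 to rank in replicate 1 was -0.35 ± 0.69 (SD, n = 151) with either 8-mer and 0.27 ± 0.64 (SD, n = 655) without, a difference of -0.61, and that of replicate 2 to replicate 1 differed the other way, by 0.36 (0.18 within the strata below). Promoter location is argued against by a difference of -0.54 among promoter regions alone, and GC content and TSS distance as its whole cause by a difference of -0.43 within strata of both, with no p given because the 8-mers were picked on these same regions. Regions were not matched for strength, and ATCGAATA was in 59.0% of the first 100 places and 2.96% of the last 406. The ranks were also not scaled to the list lengths of 2052, 1274 and 1614 regions. A dependence of the rank ratios on strength or list length therefore stays open. One hypothesis is that regions with these sequences and the other regions respond differently to the amount of tagged protein, of chromatin or of sequencing, which may differ between the libraries. None of these amounts is in the lists, so this stays open.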

How the results depend on the processing

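The settings that leave out a replicate for the shared share were chosen after seeing the data, as were all alternatives for rank agreement, list length ratios, class shares and named regions, the opposite flanks, the promoter regions against flanks, and the nearest TSS for divergence and length. The promoter share stayed above the share of bases in 12 of 12 alternatives (48.2% to 77.5%), the divergent odds ratio above 1 in 13 of 13 (2.09 to 4.89), and the log2 length difference above 0 in 12 of 12 (0.34 to 0.81). All 5 class shares passed the threshold in 9 of 9, a count that does not compare their directions. The limit of an IDR of 0.01 left nothing out, so it tests nothing. Regions in at least 2 lists numbered 1420, and the 50% of each list with the highest signal gave 480 in all 3. The mean share of the shorter list of each pair found in the longer (72.5%) was 83.4% with that 50% and 64.8% to 82.8% without each replicate, and rho (0.796) was 0.742 to 0.871. The X share of promoter regions (17.3%) passed the threshold at 19.8% in at least 2 lists (exact p = 0.025), 19.0% in the conservative list (0.048) and 19.8% in the longest list (0.0036). It fell below the reference with reciprocal overlap of 50% of each region (16.3%, exact p = 0.75), the 50% with the highest signal (14.5%, 0.24) and assembled bases as the reference (17.3%, 0.91). The cause was not tested. The number of gene lists above other genes (2) was 8 with the longest list, 0 with the 50% of highest signal, 1 with a promoter window of 200 bp, 1 with 1000 bp, 0 with the nearest TSS alone, and 1 to 2 without each replicate. The call of mitochondrial ribosomal proteins was lost in 8 of 13 alternatives, of splicing in 2 of 13, of tRNA genes in 2 of 13 and of chemoreceptors in 1 of 13; without replicate 2, cytosolic ribosomal proteins took the place of mitochondrial ones. Against offset-matched promoters, tested at the 561 promoter regions alone, 2 motifs and 53 8-mers were higher, and Tinman sites turned to -3 windows (p = 1, exact); against flanks these regions gave 8 motifs and 335 8-mers, and all 806 gave 9 and 387. The 8-mer count was 748 with the conservative list and 256 with the 50% of highest signal, where fewer regions were tested. E2F sites turned to 4 windows with the longest list (p = 0.93, exact). The named 8-mers and motifs kept their call in 194 of 234 cases. Depth is unknown, so its effect on these counts cannot be given. No paired analysis was possible because the samples form 1 group.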

Other observations

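The tests and counts of this part were chosen after seeing the data. Away from promoters, the best-ranked regions called in all 3 replicates were, after zfh1 and Asator, near CheB93a (501 bp from the TSS, ranks 46, 71 and 37, with both ATCGAATA and TATCGATA), Sox102F (669 bp, ranks 45, 74 and 80) and Adf1 (797 bp, in an intron, ranks 43, 17 and 200). Regions near HmgZ (557 bp) and ph-p (506 bp) were also among the first 10. In the 245 regions away from promoters, the CTCF site was in 18 summit windows and 2 flanks (adjusted p = 0.014, exact test), and the GAGA site (8 against 26, 0.038) and the E-box CAGCTG (12 against 31, 0.041) were less frequent at summits. In 1000 other choices of the flank side these passed in 27, 89 and 5, so these calls rest on the choice of side.

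Of the regions away from promoters, 69 of 245 were on X (28.2%, interval 22.9 to 34.1), against 17.6% of bases (exact binomial p = 4.8e-05). The share was 25% in replicate 1 (p = 9.1e-08), 26.2% in replicate 2 (p = 1.4e-06) and 19.8% in replicate 3 (p = 0.21, exact tests), so it did not pass in replicate 3. The difference between replicates was not tested.

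At equal list length, 66.0% of regions were at promoters in replicate 1, 58.4% in replicate 2 and 74.1% in replicate 3. Among regions in all 3 lists, the median fractional rank at promoters and elsewhere was 17.7% and 27% in replicate 1, 30.5% and 38.8% in replicate 2, and 24.4% and 47.5% in replicate 3. Regions in replicate 3 alone had TATCGATA in 12.8% of cases, those in replicate 1 alone in 4.15% and those in replicate 2 alone in 1.43%. Regions with a signal under 20 numbered 55, 35 and 48 in replicates 1, 2 and 3, and 54, 35 and 48 of them lay within 600 bp of a stronger region of the same list.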
